A study of Gossypium hirsutum with 6 samples.

How the data were processed

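Leaf mRNA of upland cotton (*Gossypium hirsutum*) seedlings about 20 days old was measured by sequencing on an Illumina HiSeq instrument, in 6 libraries. Per the labels' protocols, the seedlings grew at 28 °C by day and 22 °C by night under 14 h of light and 10 h of dark. Heat at 45 °C began in the middle of the day and lasted 4 or 8 h, and the control stayed at 28 °C. RNA came from a modified CTAB extraction with column clean-up, followed by standard Illumina library preparation. The libraries were grouped by the genotype, phenotype and treatment given in the labels, which made 6 groups with 1 library each.

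The values are RPKM (read counts divided by transcript length and by the size of the library) with 2 decimals, as the authors deposited them, with 1 RPKM column per library. Every column lists the same 421554 transcripts. The assembler, aligner, counting program, strand setting and annotation are not given in the sources used here. The transcript identifiers have the form of a de novo assembly, in which a component gathers transcripts assembled together. There were 148415 components, of which 107480 held 1 transcript, while the largest held 154. The files do not pair these identifiers with gene names, and 0 of them matched the 99454 genes of the reference table (assembly Gossypium_hirsutum_v2.1). The 47 gene lists fixed before the data were examined were therefore not applied, and no gene is named.

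RPKM can be compared between libraries only as a share of all reads, so a fall of abundant transcripts raises the values of the rest. Many transcripts also share a profile. Of 3306 transcripts at 10 RPKM or more in all 6 libraries, 985 (29.8%) had a partner in another component whose values were proportional over the 6 libraries within a distance of 0.02 (Euclidean, on centred natural logarithms). After each library was permuted the number was 0. The transcript comp102481_c0_seq1, for example, stood at 1.00757 to 1.00795 times a transcript of another component in every library. How reads were assigned was not examined, so a count of transcripts may exceed the number of loci behind it. A count over components (the transcript with the highest mean RPKM of each), chosen after the data were examined, is given beside it. It does not remove partners that lie in other components.

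The total number of reads is unknown. Relative depth was recovered from the spacing of the low values, because a transcript's smallest step in RPKM is the worth of 1 read and scales inversely with depth. The 15 pairs of libraries gave depths that agreed to within 0.00657 on the log2 scale. No counting interval is given, because it needs the read counts themselves. A value of 0 is reported as listed at 0.

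For each of 9 comparisons the log2 ratio of (RPKM + 1) was taken over transcripts at 1 RPKM or more in either library, and transcripts at least 2-fold apart on that scale were counted. This scale understates ratios of low transcripts. Folds given for single transcripts are plain ratios of RPKM. With 1 library per group a single comparison or the interaction of genotype and heat has no spread to be tested against, so no p-value is given. An additive model of genotype and condition over the 6 libraries, which would test averaged effects, was not run. The size rule says nothing of the spread between plants. For the difference of heat response, the log2 ratio in the sensitive genotype was subtracted from that in the tolerant genotype, and differences of at least 1 were counted. Correlations of the responses run across transcripts, which are not independent replicates. Overlaps of lists that share a control library were set beside the overlap of independent lists. They were also set beside 20 simulations of unchanged libraries against the same control. The simulated noise was taken from the tolerant less the sensitive control library, for both genotypes. It therefore holds differences between the genotypes and a fixed sign, so the simulated overlaps are not values of chance alone. Sizes of the simulated lists were not matched to those observed, so these overlaps do not measure what a shared control adds.

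The alternatives were a pseudocount of 0.1 RPKM, a filter of 5 RPKM, no filter with a pseudocount of 0.1, median-of-ratios scaling and upper-quartile scaling (75th percentile) between the 6 libraries. The scaling factors were computed without the filter of 1 RPKM, so a gain of low transcripts in a library enters its factors. They were highest in the tolerant 4 h and sensitive 8 h libraries, at 1.32 and 1.25 (median-of-ratios) and 1.20 in both (upper-quartile). These libraries also held the most transcripts at 1 RPKM or more. Counts of transcripts past a limit under all 3 scalings (as deposited, median-of-ratios and upper-quartile) were added after the data were examined, as were the 8-fold limit, the set of transcripts abundant in both controls, a baseline that averages both controls, and a merging of transcripts with proportional values.

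The rule for named items, fixed before the data were examined, took the 8 highest and 8 lowest log2 ratios of each comparison among genes at 10 RPKM or more with a described protein, and the 3 highest RPKM of each library. The part on described proteins was not applied. Identifiers are given for 4 transcripts among the 3 highest of a library, chosen after their values were seen, and the other extremes are described without identifiers.

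The procedure was tested on simulated data made from the tolerant control, with 200 transcripts altered. With the altered transcripts at 1 to 10 RPKM, in a comparison over 109664 transcripts of any level, 100% of those raised 4-fold and 52% of those lowered 4-fold were found. With the altered transcripts at 10 RPKM or more, in a comparison over 109720 transcripts, both shares were 100%. The simulated noise of 0.1 on the log2 scale is too small for chance to pass the 2-fold limit, so these runs say nothing of false calls. The real controls were 2-fold apart for 8.50% of the transcripts compared. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.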

Results

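Leaf transcripts of 2 upland cotton genotypes were compared at 28 °C and after 4 and 8 h at 45 °C. The labels describe Nan Dan Ba Di Da Hua as heat tolerant and Earlistaple 7 as heat sensitive. The design asks how the leaf transcriptome of each genotype differs under heat, and where the genotypes differ from each other. Each group held 1 library, so every value below is that of a single library and the spread between plants is unknown. The labels do not say at which hour the control leaves were taken, so hours of heat and time of day are not separated.

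Relative to the tolerant control, read depth was 0.803 and 0.793 in the tolerant 4 h and 8 h libraries, and 1.13, 1.07 and 0.870 in the sensitive control, 4 h and 8 h libraries. The number of transcripts at 1 RPKM or more was 107290 in the tolerant control, 147583 at 4 h and 120293 at 8 h. In the sensitive genotype it was 114604, 119524 and 148293. Transcripts at 100 RPKM or more numbered 775, 431 and 599 in the tolerant genotype and held 26.7%, 15.3% and 24.3% of all RPKM. In the sensitive genotype they numbered 661, 589 and 518 and held 25.3%, 19.8% and 13.4%. Across 226960 transcripts at 1 RPKM or more in any library, the controls of the genotypes correlated at Pearson's r = 0.907 (Spearman's rho = 0.85) on the log2(RPKM + 1) scale. The tolerant control correlated at r = 0.709 with its 4 h library and 0.468 with its 8 h library, and the sensitive control at 0.747 and 0.686 with its own. With the sensitive 4 h and 8 h libraries the tolerant control correlated at 0.785 and 0.735, and the tolerant 4 h library at 0.882 and 0.843. The tolerant 8 h library correlated at 0.716 with the tolerant 4 h, 0.646 with the sensitive 4 h and 0.701 with the sensitive 8 h library. Transcripts are not independent replicates in these correlations.

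The most abundant transcript of each heated library was at least 64.9-fold higher there than in its control. comp102481_c0_seq1, the highest transcript of the tolerant 4 h library and of both heated sensitive libraries, stood at 43.1 RPKM in the tolerant control, 5259.14 at 4 h and 3429.58 at 8 h, 122-fold and 79.6-fold higher. In the sensitive genotype it went from 30.42 RPKM to 5713.84 and 1974.84, 188-fold and 64.9-fold higher. Its ratio to a transcript of another component stayed between 1.00757 and 1.00795 in all 6 libraries. So narrow a range argues against separately drawn reads behind both, although how reads were assigned was not examined. comp104672_c0_seq9 was the highest transcript of the tolerant 8 h library. It measured 6.59, 2172.43 and 4387.01 RPKM in the tolerant control, 4 h and 8 h libraries against 2.41, 863.38 and 786.03 in the sensitive ones, so that at 8 h it was 5.58-fold higher in the tolerant genotype.

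The 4 transcripts among the 3 most abundant of either control were lower after heat in both genotypes. comp95781_c0_seq1, the highest transcript of both controls, measured 7185.69, 913.98 and 124.1 RPKM in the tolerant control, 4 h and 8 h libraries. The sensitive libraries gave 5166.93, 2725.61 and 98.6 RPKM. At 4 h it was therefore 7.86-fold lower in the tolerant and 1.90-fold lower in the sensitive genotype, while at 8 h the folds were 57.9 and 52.4. comp115063_c1_seq2 measured 2928.06, 432.61 and 25.86 RPKM in the tolerant and 2861.95, 1112.12 and 629.38 RPKM in the sensitive libraries. After 8 h it was 24.3-fold lower in the tolerant than in the sensitive genotype. The 2 other transcripts among the 3 highest of a control were lower in all heated libraries too. One, of the same component, measured 2675.88, 334.92 and 20.91 RPKM in the tolerant and 2616.15, 811.83 and 458.07 RPKM in the sensitive libraries, and the other 3044.58, 423.6 and 54.03 RPKM and 2190.6, 1234.49 and 45.83 RPKM.

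**Figure D1:**
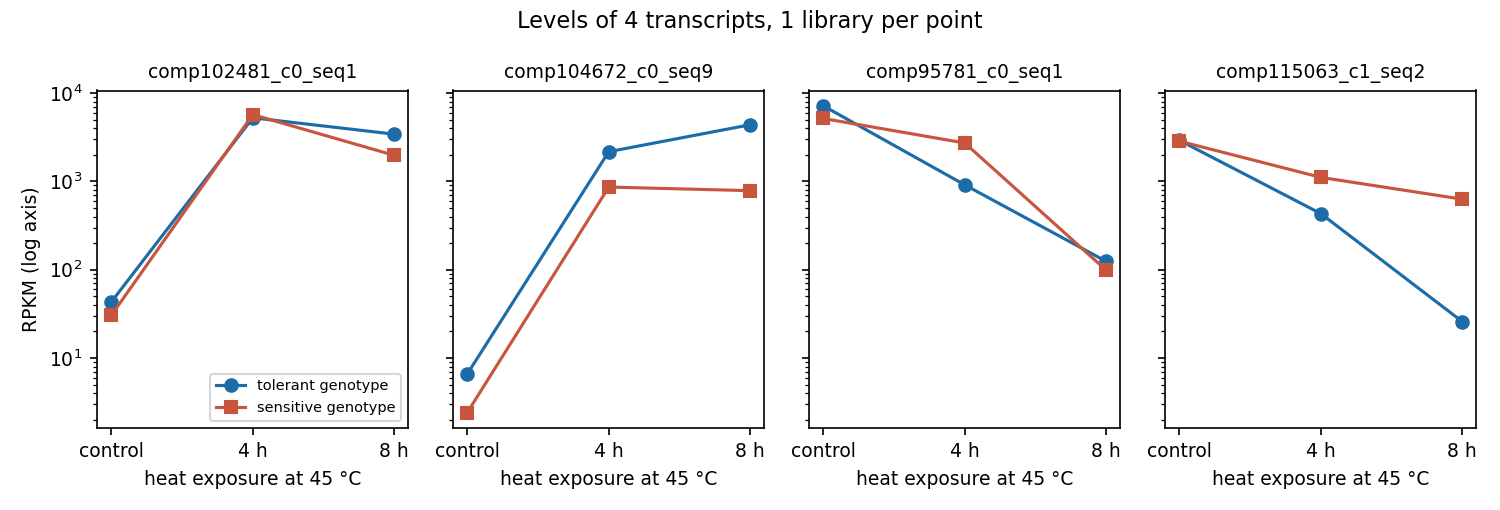
RPKM (log axis) of 4 transcripts in the control, 4 h and 8 h libraries of the tolerant genotype (circles) and the sensitive genotype (squares), with 1 library per point and no error bars. comp102481_c0_seq1 and comp104672_c0_seq9 lie at 786.03 RPKM or above in every heated library, and comp115063_c1_seq2 ends at 25.86 RPKM in the tolerant and 629.38 RPKM in the sensitive genotype at 8 h.

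After 4 h of heat in the tolerant genotype, 35092 of 169875 transcripts were at least 2-fold higher and 15537 at least 2-fold lower than in the control. Over components the counts were 18200 and 8514. The 8 highest log2 ratios lay between 8.16 and 9.34, led by a transcript at 0.19 RPKM in the control and 768.93 RPKM at 4 h. The 8 lowest lay between -6.83 and -6.36, led by a transcript at 554.15 RPKM in the control and 3.88 RPKM at 4 h. The balance of directions turned with the scaling, with 15632 higher and 27424 lower under median-of-ratios scaling and 19207 and 25779 under upper-quartile scaling. The factors of these scalings shifted the log2 ratio of RPKM by -0.63 and -0.52, and the ratio of (RPKM + 1) by less where values were low. Shifts given for the other comparisons are those of the factors. Under all 3 scalings 15632 transcripts were at least 2-fold higher and 15537 lower, and 280 were at least 8-fold higher and 901 lower. Each direction is limited by the scaling least favourable to it, so the balance of such counts need not be that under any single scaling.

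After 8 h in the tolerant genotype, 45233 of 164561 transcripts were at least 2-fold higher than in the control and 34182 lower, together 48.3% of those compared. Over components the counts were 23028 and 17004, an order that turned to 5960 and 7146 with a filter of 5 RPKM. Under all 3 scalings 42551 were higher and 33695 lower, of which 1864 and 2455 differed by at least 8-fold. The highest log2 ratios ran from 8.82 to 9.33 and the lowest from -7.98 to -7.38. The transcript with the lowest ratio measured 398.53 RPKM in the control, 29.03 at 4 h and 0.58 at 8 h in the tolerant genotype, against 167.92, 27.85 and 12.27 RPKM in the sensitive genotype. The scalings shifted this comparison by 0.10 (median-of-ratios) and -0.20 (upper-quartile) on the log2 scale.

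Between 4 and 8 h in the tolerant genotype, 19321 of 177741 transcripts were higher at 8 h and 29691 lower, or 11876 and 16796 components. Median-of-ratios scaling gave 38843 higher and 10430 lower, and upper-quartile scaling 25116 and 17601, with shifts of 0.73 and 0.32. The larger ratios leaned to higher values at 8 h. As deposited, 571 transcripts were at least 8-fold higher and 158 lower, and under all 3 scalings 571 and 54. Of 197595 transcripts compared at both times against the control, 16330 were higher at both, 18621 at 4 h alone and 28779 at 8 h alone. A further 13294 were lower at both, 2135 at 4 h alone and 20754 at 8 h alone. The numbers shared between the times compare with 8019 higher and 2683 lower for independent lists, and with means of 394 and 2573 in simulations of unchanged libraries against the shared control. Part of the excess may come from that control, and the simulated noise also holds differences between the genotypes. How large that part is cannot be read from the simulations, whose lists were not held to the observed sizes.

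In the sensitive genotype, 19226 of 149336 transcripts were at least 2-fold higher after 4 h and 16147 lower, which is 9575 and 8381 components. The transcript leading at 4 h in the tolerant genotype led here too, with 0.13 RPKM in the control and 383.27 RPKM at 4 h. The lowest ratio belonged to a transcript at 346.34 RPKM in the control and 3.23 RPKM at 4 h, which went from 313.06 to 1.96 RPKM in the tolerant genotype. Under all 3 scalings 17524 transcripts were higher and 16147 lower, with 972 and 619 past 8-fold. The scalings shifted this comparison by -0.08 each, which left the directions nearly even, with 17524 higher and 17842 lower (median-of-ratios) and 18946 and 18990 (upper-quartile).

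After 8 h in the sensitive genotype, 32294 of 172047 transcripts were at least 2-fold higher and 14194 lower, or 17945 and 7408 components. The highest ratio was that of a transcript at 0.2 RPKM in the control, 94.59 at 4 h and 843.14 at 8 h, whose values in the tolerant genotype were 0.68, 34.92 and 16.35 RPKM. The scalings brought the directions close to balance, with 20454 higher and 19381 lower (median-of-ratios) and 21153 and 21215 (upper-quartile), after shifts of -0.37 and -0.41. Under all 3 scalings 20293 were higher and 14194 lower, and 1132 and 820 differed by at least 8-fold.

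Between 4 and 8 h in the sensitive genotype, 14350 of 161899 transcripts were higher at 8 h and 3589 lower, together 11.1%, against 27.6% in the tolerant genotype. Over components the counts were 9917 and 2535. The scalings, which shifted the ratios by -0.29 and -0.33, gave 7971 and 5125, and 8279 and 6080. Of 180979 transcripts compared at both times against the control, 12739 were higher at both, 6429 at 4 h alone and 19519 at 8 h alone. Those lower numbered 10152 at both times, 5962 at 4 h alone and 4000 at 8 h alone. Independent lists would share 3423 and 1264, and simulated unchanged libraries shared 631 and 2507 on average, in lists not held to the observed sizes. The simulated noise kept the sign of the tolerant less the sensitive control, so this split is not that of unchanged sensitive libraries. The lists lower than control at 8 h alone thus held 20754 transcripts in the tolerant and 4000 in the sensitive genotype, a difference that was not tested. Counts by time in both genotypes are of values as deposited and were not recomputed under the scalings. Median-of-ratios scaling took the tolerant list lower at 4 h from 15537 to 27424, so these counts need not hold there.

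**Figure D2:**
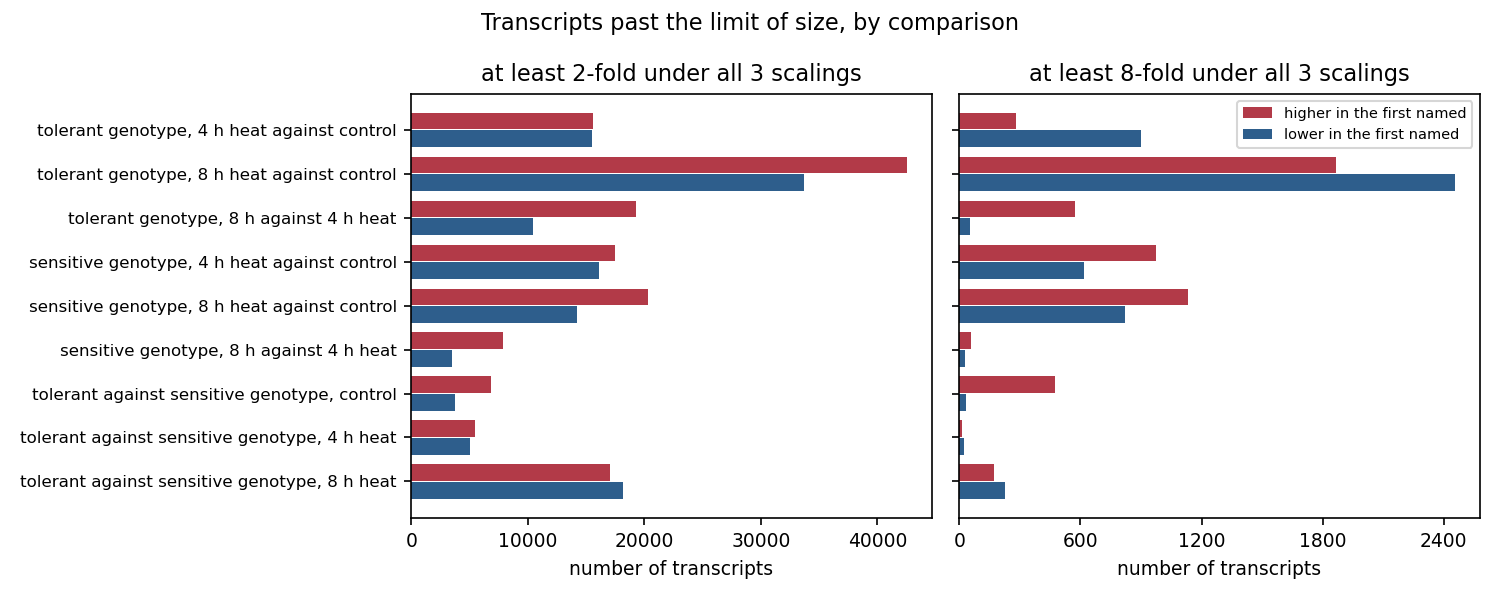
Number of transcripts at least 2-fold (left) and at least 8-fold (right) higher or lower in the first named library of each of 9 comparisons, counted only where the limit was passed under all 3 scalings, with 1 library per group. The tolerant 8 h against control comparison has the longest bars, with 42551 higher and 33695 lower at 2-fold. The balance of a pair of bars need not be that under any single scaling.

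Most transcripts abundant in unheated leaves were lower after heat than in their own control, and more so in the tolerant genotype. A difference between the controls enters these ratios and was not separated from a difference in response. Over the 684 transcripts with a mean of 100 RPKM or more in the controls, the median log2 ratio to control was -2.53 at 4 h and -4.21 at 8 h in the tolerant genotype. In the sensitive genotype the medians were -1.58 and -2.35. The ratio was lower in the tolerant than in the sensitive genotype for 589 of the 684 transcripts (86.1%) at 4 h and for 573 (83.8%) at 8 h. Over components it was lower for 413 of 481 at 4 h and 408 of 481 at 8 h. At 8 h the share was 77.2% under median-of-ratios and 81.6% under upper-quartile scaling, and at 4 h the numbers were 650 and 646 of 684. At 8 h 585 of the transcripts were at least 2-fold lower in the tolerant genotype and 510 in the sensitive one, 499 of them in both.

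The same order held when each genotype's transcripts were classed by their level in the control of the other genotype, which keeps the class free of the control in the ratio. The classes of the genotypes hold different transcripts, however. A transcript high in the tolerant control alone enters only the class of the sensitive genotype. The controls differed one-sidedly, with 472 transcripts at least 8-fold higher in the tolerant and 34 in the sensitive control. That difference may therefore still enter this comparison. The 661 transcripts at 100 RPKM or more had medians of 180, 31.9 and 8.62 RPKM in the tolerant control, 4 h and 8 h libraries. Their share of all RPKM went from 23.9% to 6.72% and 4.92%. The corresponding 775 transcripts in the sensitive genotype had medians of 163, 68.2 and 54.8 RPKM and shares of 25.1%, 12.8% and 9.39%. At 8 h 18.7% of these 775 were at least 2-fold higher than in control, against 4.69% of the 661. At the other end, of 79192 transcripts below 0.1 RPKM in the sensitive control, 8.71% were at least 2-fold higher at 4 h and 18.3% at 8 h in the tolerant genotype. Of 92008 transcripts below 0.1 RPKM in the tolerant control, 2.78% and 8.79% were higher in the sensitive genotype. These shares are of RPKM as deposited and were not recomputed under the scalings.

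**Figure D3:**
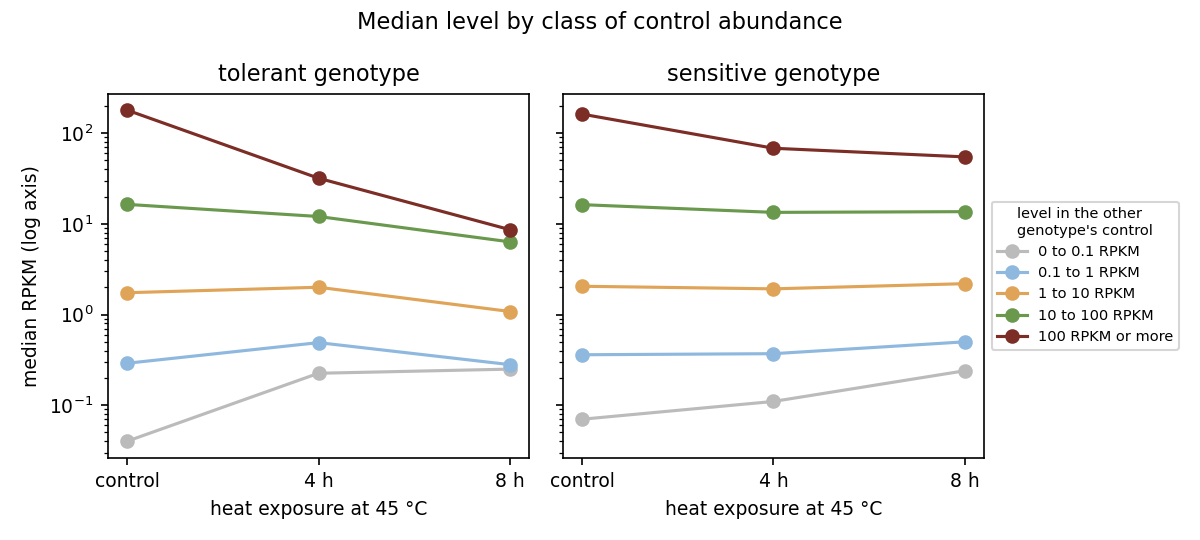
Median RPKM (log axis) in the control, 4 h and 8 h libraries of transcripts in 5 classes set by their RPKM in the control of the other genotype, for the tolerant genotype (left) and the sensitive genotype (right), with 1 library per point. The class at 100 RPKM or more ends at 8.62 RPKM in the tolerant and 54.8 RPKM in the sensitive genotype at 8 h.

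Without heat the genotypes were close, with 6861 of 129908 transcripts (5.28%) at least 2-fold higher in the tolerant and 4187 (3.22%) higher in the sensitive genotype. Over components the counts were 3774 and 2902. A filter of 5 RPKM gave 2806 and 688 transcripts, while no filter with a pseudocount of 0.1 turned the balance to 37389 and 43678. The large differences were one-sided, with 472 transcripts of 284 components at least 8-fold higher in the tolerant control and 34 of 26 components in the sensitive control. The 472 had medians of 30.2 RPKM in the tolerant and 1.41 RPKM in the sensitive control, a gap that their selection favours. After heat their medians were lower in the tolerant than in the sensitive genotype, at 7.78 against 16.3 RPKM at 4 h and 11.9 against 23.2 RPKM at 8 h. The leading one measured 93.83 RPKM in the tolerant and 0.7 RPKM in the sensitive control. In the other direction the leading transcript was listed at 0 in the 3 tolerant libraries and measured 100.6, 44.45 and 69.23 RPKM in the sensitive control, 4 h and 8 h libraries. The scalings shifted this comparison by 0.18 and 0.11, and under all 3 scalings 472 and 32 transcripts were 8-fold apart.

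At 4 h the genotypes were again close, with 12594 of 161973 transcripts higher in the tolerant and 5171 higher in the sensitive genotype, or 8668 and 3489 components. This balance turned to 5426 and 8083 under median-of-ratios and to 6715 and 8424 under upper-quartile scaling, with shifts of -0.36 and -0.33. At least 8-fold apart were 21 transcripts in each direction, and 12 and 21 under all 3 scalings. At 8 h 17085 of 179205 transcripts were higher in the tolerant and 35776 higher in the sensitive genotype, or 10627 and 19775 components. The scalings, with shifts of 0.65 and 0.32, gave 37657 and 18135, and 24244 and 23745. At least 8-fold apart at 8 h were 173 and 575 transcripts. Under all 3 scalings the counts at 8 h were 17085 and 18135, with 173 and 225 transcripts past 8-fold. The leading transcript in the sensitive direction measured 547.82, 191.77 and 4.52 RPKM in the tolerant and 302.8, 402.67 and 485.3 RPKM in the sensitive control, 4 h and 8 h libraries. The leading one in the tolerant direction was listed at 0 in both controls and measured 65.74 RPKM in the tolerant and 0.66 RPKM in the sensitive 8 h library.

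The heat responses of the genotypes ran together across transcripts, with r = 0.617 (rho = 0.587) at 4 h and r = 0.595 (rho = 0.558) at 8 h. No library is shared between the ratios correlated, and the r were 0.611 and 0.616 under median-of-ratios scaling. At 4 h 9524 transcripts were at least 2-fold higher and 7716 lower in both genotypes, where independent lists would share 3556 and 1323. At 8 h the shared numbers were 13966 higher and 9462 lower, against 7069 and 2347 for independent lists. Opposite responses were fewer than independent lists would give. At 4 h 701 transcripts were lower in the tolerant and higher in the sensitive genotype and 172 the reverse, against 1575 and 2988. With a pseudocount of 0.1 that order turned, to 2444 and 4074. At 8 h they numbered 1540 and 101, against 5341 and 3106, and 8055 and 1994 with a pseudocount of 0.1.

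The response differed by at least 1 on the log2 scale for 32438 of 189246 transcripts at 4 h, 20997 of them with the greater log2 ratio in the tolerant genotype. At 8 h it differed for 58440 of 206362, of which 21214 had the greater ratio in the tolerant and 37226 in the sensitive genotype. Both scalings turned this balance at 4 h, and median-of-ratios scaling turned it at 8 h. Under median-of-ratios scaling the greater ratio lay in the tolerant genotype for 10062 and in the sensitive for 19403 transcripts at 4 h, and for 39885 and 26675 at 8 h. Under upper-quartile scaling the numbers were 12701 and 18327 at 4 h and 28095 and 31163 at 8 h. The 8 most negative differences at 8 h ran from -8.07 to -7.27, led by a transcript at 47.59, 1.56 and 1.44 RPKM in the tolerant and 0.75, 2.38 and 22.57 RPKM in the sensitive control, 4 h and 8 h libraries. The 8 most positive ran from 4.23 to 5.49, led by a transcript at 90.21 RPKM in the tolerant and 1.45 RPKM in the sensitive 8 h library.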

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

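The tests with an averaged control and with merged transcripts were added after the data were examined, each with its limits set before its own result was seen. A group of 373 transcripts from 208 components was at least 2-fold lower after heat in the tolerant genotype and at least 2-fold higher in the sensitive genotype at both times, and 11 transcripts went the other way. They stand out because the direction of the response is opposite in the genotypes. The difference was not tested, since each group has 1 library and both times share a control. The 373 had medians of 17.66, 4.56 and 3.41 RPKM in the tolerant control, 4 h and 8 h libraries and of 1.27, 11.13 and 14.84 RPKM in the sensitive ones. Their selection favours a high tolerant and a low sensitive control, so these medians do not show that the controls differ.

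At 8 h, 1540 transcripts were lower in the tolerant and higher in the sensitive genotype and 101 the reverse, a ratio of 15.2, which was 4.04 with a pseudocount of 0.1 (8055 against 1994) and 2.82 over components with that pseudocount. Scaling alone is argued against as the whole cause by a ratio of 5.50 under the scaling that lowered it most, although components under median-of-ratios scaling gave 3.82. Repeated counting of loci alone is argued against by a ratio of 10.0 over components, and of 8.35 (676 against 81) after merging transcripts of a component and transcripts of any component with values proportional within a distance of 0.2. A difference between the control libraries cannot be told apart from a difference in response, since the ratio against the average of both controls was 11.8 as deposited (414 against 35) but 1.89 under median-of-ratios (166 against 88) and 3.66 under upper-quartile scaling. By the limits set beforehand, the 1.89 falls on the side of a control difference as the cause and the 11.8 on the other side. Of the 1540, 1114 (72.3%) were at least 2-fold higher in the tolerant than in the sensitive control, a share that their selection favours.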

How the results depend on the processing

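The settings in this part were planned. Both scalings left the 9 counts of transcripts at least 2-fold apart, both counts of response differences and the 4 correlations within the tolerance used (1.5 times for counts, 0.05 for correlations), but they moved the balance of directions as given beside each comparison. In the order tolerant 4 h and 8 h against control and 8 h against 4 h, then the same for the sensitive genotype, then tolerant against sensitive in control, at 4 h and at 8 h, a filter of 5 RPKM gave 16640, 25474, 15570, 14400, 15938, 4001, 3494, 4294 and 16232 transcripts, because fewer transcripts were compared. No filter with a pseudocount of 0.1 gave 188221, 225089, 183027, 147732, 161994, 102622, 81067, 107217 and 184439, where both the filter and the pseudocount differ. A pseudocount of 0.1 alone, which stretches ratios of low transcripts, gave 91727 for the tolerant genotype at 4 h and 92194 for its 8 h against 4 h. It gave 66023, 81077 and 40953 in the sensitive genotype and 23743, 42202 and 94690 between genotypes. Differences of response numbered 71550 and 114697 at 4 and 8 h with that pseudocount, and 8986 and 20605 with the filter of 5 RPKM. The Pearson correlation of responses at 4 h was 0.536 with the pseudocount. With the filter of 5 RPKM, Pearson and Spearman values were 0.706 and 0.708 at 4 h and 0.691 and 0.698 at 8 h. Among the log2 ratios of the 4 named transcripts 1 sign turned: comp102481_c0_seq1 at 8 h against 4 h in the tolerant genotype, lower at -0.62, stood at 0.11 under median-of-ratios scaling, whose shift of 0.73 exceeds the difference. Balances of higher against lower counts that turned are given beside their comparisons. The balance of response differences at 4 h also turned with the filter of 5 RPKM, to 3993 and 4993, and the cause was not tested. Of 351 other values, 233 stayed within tolerance and 117 moved past it. The ratios of the 4 named transcripts were computed without a filter, and the filter left the class medians at 100 RPKM or more unchanged. Their values with a filter of 5 RPKM therefore repeat the main ones, and those with no filter repeat the pseudocount of 0.1. The 233 thus overstates how stable these values are. The counting interval and the gene list medians were not run, since they need read counts and gene names. The total depth is unknown, so its limit for low transcripts was not computed. With the pseudocount of 1, 52% of simulated 4-fold decreases were found at 1 to 10 RPKM in the tolerant control.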

Other observations

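The test of a genotype label swap, the depth test on the number of transcripts, the test of share freed by abundant transcripts for each library and the test of a like gain in every class were chosen after the results were seen, as were all the sets described here. A set of 42 transcripts from 37 components was at 10 RPKM or more in all 4 heated libraries and below 1 RPKM in both controls. Its medians were 0.535, 30.0 and 61.4 RPKM in the tolerant control, 4 h and 8 h libraries and 0.16, 23.5 and 38.7 RPKM in the sensitive ones. The opposite set, at 10 RPKM or more in both controls and below 1 RPKM in the 4 heated libraries, held 48 transcripts from 29 components. Its medians were 18.4, 0.35 and 0.24 RPKM in the tolerant and 24.2, 0.435 and 0.135 RPKM in the sensitive genotype.

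The tolerant 8 h library held 1307 transcripts at more than 10 times their level in each of the 5 other libraries, against 111 to 497 in the other libraries. Of these, 92 from 70 components reached 10 RPKM, with a median of 22.6 RPKM there, 1.44 RPKM in the sensitive 8 h library and 0.675 RPKM in the tolerant 4 h library, while both controls had a median of 0. Such transcripts at 10 RPKM numbered 16 in the tolerant control, 2 in the sensitive control, 1 in the sensitive 8 h library and 0 in both 4 h libraries. The tolerant 8 h library also listed 381 transcripts at 0 that were at 1 RPKM or more in the 5 others, against 6 to 65 elsewhere.

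Genotype differences that held in all 3 conditions covered 252 transcripts of 168 components higher in the tolerant and 280 of 206 components higher in the sensitive genotype. Independent lists would share 28.6 and 15. There were 5 transcripts from 3 components at 10 RPKM or more in all 3 sensitive libraries and listed at 0 in all 3 tolerant ones, and 0 in the reverse. At 1 RPKM or more the numbers were 38 and 15.

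The tolerant 8 h library lay farther from its control than the sensitive 8 h library did, with 79415 against 46488 transcripts at least 2-fold apart. Scaling is argued against, since the ratio of these counts, 1.71, was at least 2.03 under either scaling. The other settings lowered it. The counts were 114786 against 81077 with a pseudocount of 0.1 and 25474 against 15938 with a filter of 5 RPKM. With no filter and a pseudocount of 0.1 they were 225089 against 161994, and 94950 against 80088 over components. The test of read depth did not decide. At a mean of 10 RPKM or more, where counting error is small, the ratio was 1.33 (7442 against 5585 of 11594), between the limits set beforehand. The tolerant 4 h library, however, had nearly the depth of the 8 h library, 0.803 against 0.793 of their control. Against that control 29.8% of transcripts were 2-fold apart at 4 h and 48.3% at 8 h, which argues against depth as the whole cause. A swap of genotype labels at 8 h is argued against by genotype markers, of which 98.2% were higher in the library of their genotype. A genotype difference in the heat response, the hour of harvest, differences between single plants and RNA quality stay open and untested.

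More transcripts reached 1 RPKM in the tolerant 4 h and sensitive 8 h libraries than in their controls, 1.38 and 1.29 times as many. Deeper reading is not the cause, since both were read less deeply than their controls, at 0.803 and 0.767 of the depth. Shallower reading adds counting error, which could carry low transcripts past 1 RPKM, and that was not tested. The tolerant 8 h library, at a like depth of 0.793, held 1.12 times as many as its control. After division by the share that abundant transcripts gave up, the ratio was 1.14 in the tolerant 4 h library, which leaves an excess. In the sensitive 8 h library it was 1.07. The divisor counts transcripts that became abundant under heat among the rest, so it may be too large. In the tolerant 8 h library it took the ratio from 1.12 to 0.937. How much of the excess in the sensitive 8 h library that share accounts for is therefore not settled. A like amount of signal added to every transcript cannot be told apart from a gain in many of them. The median gain was 0.185, 0.20 and 0.26 RPKM in transcripts below 0.1, at 0.1 to 1 and at 1 to 10 RPKM for the tolerant and 0.17, 0.14 and 0.14 RPKM for the sensitive library, and the gains differed by at most 1.41 times. The lower quartile of the log2 ratio was 0 or below in these classes, however, and the gain was -4.35 and -2.66 RPKM in transcripts at 10 to 100 RPKM, where decreases would hide such a gain.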
